A study of Mus musculus with 11 samples.

How the data were processed

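The study measured messenger RNA in mouse embryos at E9.5, with 21 to 23 pairs of somites, that carried a Stag2 knockout (KO) or were wild type (WT). Per the labels, the heart was taken with the second heart field around it, and the neural tube was taken at the level of the heart. They state 3 replicates for each genotype and tissue, with 3 embryos in each, and the separateness of the replicates rests on that statement. Libraries were made with a QuantSeq 3′ FWD kit, which reads tags near the 3′ end of a transcript. The table deposited by the authors holds raw counts per Ensembl mouse gene identifier, with no normalization. The values were whole numbers, and no column was left unused. The processing notes name the mm10 genome build and DESeq2 without a role or a version. The aligner, the counting tool, the annotation release and any use of molecular identifiers are not given in the sources used here.

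The table held 47643 genes, of which 47224 identifiers matched a symbol in the GENCODE M21 annotation of the same build (GRCm38), which also gave the positions. The 11 libraries formed 4 groups, namely KO heart, WT heart, KO neural tube and WT neural tube. WT heart held 2 libraries, and WT heart replicate 3 was not analysed here. Total counts ran from 4239470 to 7730584 per library. Genes were kept by the filterByExpr function of edgeR 4.0.16 with a minimum count of 10 over the 4 groups, which left 14226 genes. Libraries were scaled with TMM, and 1 quasi-likelihood model of the 4 groups was fitted to all 11 libraries (estimateDisp, robust glmQLFit, glmQLFTest) in R 4.3.3. The biological coefficient of variation was 0.279. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons were KO against WT in heart, KO against WT in neural tube, the mean of both genotype differences, the difference between them, heart against neural tube in WT, and heart against neural tube in KO. All p-values of these models measure the spread between these samples, estimated over all 11 libraries together. Those for heart thus rest in part on the spread among neural tubes, and WT heart adds only 2 libraries. The replicate numbers do not say which embryos gave a library, so they were not used to pair samples.

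Fold changes are log2 values of KO over WT or of heart over neural tube with their standard error (SE), the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, as mean and standard deviation (SD) over the libraries of a group. A fold against a group with no counts is a lower bound computed against 3 counts over the group, and a ratio with few counts carries an exact binomial interval at 95% confidence. Intervals and floors cover counting error only, since reads are not shown to be independent molecules.

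The gene lists, the tests, the comparisons, most alternatives and the rule for named genes were chosen before the data were examined. The rule took the 10 genes higher and the 10 lower with the largest change among called genes with a gene name, no overlap between the KO and WT libraries and at least 10 CPM in the higher group. From each gene list it took up to 4 members past the threshold, or up to 2 abundant members as values. In the tissue comparison it took 5 genes each way, and where no gene was called it took the 5 genes with the smallest p. Any other gene in the text was chosen after its values were seen. The 38 gene lists covered cohesin, heart and neural tube cell types, neighbouring tissues, signalling pathways, the cell cycle, metabolism and embryo stage and sex. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, with an estimated correlation and with fry, and adjusted over the lists. Members were also adjusted over the list alone with the edgeR p-values. This was done within each list and not across the 38 lists, so such a pass is weaker than a call over all genes. The models were tested on simulated data before the real comparisons, with counts drawn from the means, spread and library sizes of these samples and 200 genes changed by known fold changes.

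The alternatives were DESeq2 1.42.0 with its size factors, RLE scaling, no filter, a stricter filter of 5 CPM in 3 libraries, haemoglobin and mitochondrial genes left out, limma-trend, a log2 fold change of at least 1 beside the adjusted p, a fit of only the compared groups, the replicate number as a block, and leaving out each library in turn. After the data were seen, 4 alternatives were added. These were the main axis of variation among neural tube libraries as a covariate, the ribosomal RNA gene model Gm42418 left out of the library sizes, voom with sample quality weights, and leaving out each library for the lists of the mean and of the difference.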

Results

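Messenger RNA was counted with 3′ tags in the heart region and in the heart-proximal neural tube of Stag2 KO and WT mouse embryos at E9.5. The groups were KO heart with 3 libraries, WT heart with 2, KO neural tube with 3 and WT neural tube with 3. Total counts per library ran from 4239470 to 7307513 in KO heart and from 6194737 to 6923559 in WT heart. They ran from 6921822 to 7730584 in KO neural tube and from 5350787 to 6459676 in WT neural tube. Between 16631 and 18461 genes had counts in a library, and both WT hearts lay at the low end with 16816 and 16631. No pair of replicates was identical, and their rank correlation across genes, which are not independent replicates, ran from 0.938 to 0.982. The first principal component held 51.6% of the variance and parted hearts from neural tubes, and the second held 15.2%. The third held 8.51% and set WT heart 1 (-58.0) apart from WT heart 2 (54.2).

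**Figure D1:**
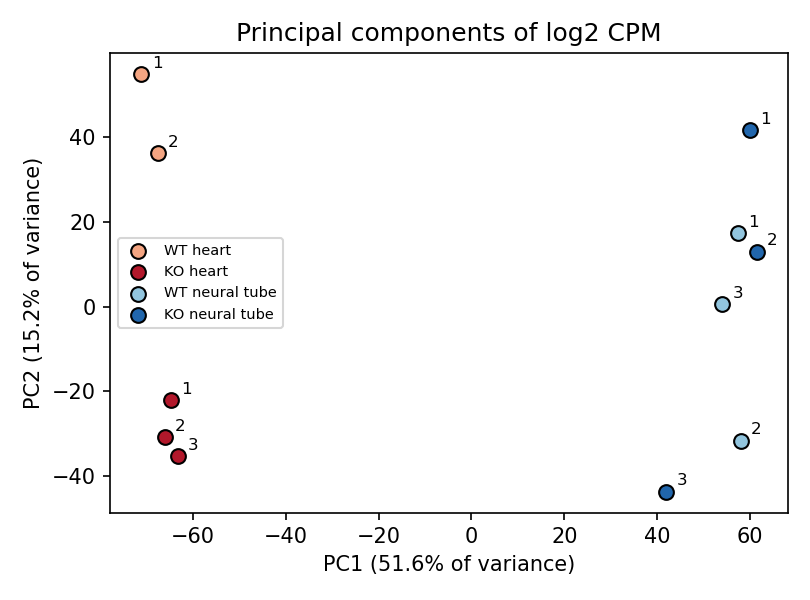
Principal components of log2 CPM for the 11 libraries, 1 point per library coloured by group, with the percent of variance on each axis. The first component, with 51.6% of the variance, parts heart from neural tube.

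The level of Stag2, which encodes a subunit of the cohesin ring that holds and folds chromatin, was compared first, since it checks the genotype of each library. Stag2 (ENSMUSG00000025862, chromosome X, 42149317 to 42277185 in GRCm38, plus strand) lay at 59.3, 53.8 and 58.8 CPM in the KO hearts and at 77.8 and 77.3 CPM in the WT hearts. In the neural tubes it lay at 43.0, 45.4 and 44.4 CPM in KO and at 80.5, 73.0 and 77.1 CPM in WT. Every KO library was below every WT library of its tissue, and each library held between 215 and 536 tags of the gene. The group means were 57.3 ± 3.07 CPM (SD, n = 3) against 77.5 ± 0.34 (SD, n = 2) in heart and 44.2 ± 1.22 (SD, n = 3) against 76.9 ± 3.80 (SD, n = 3) in neural tube. The KO level was thus 74.0% of WT in heart (log2 fold change -0.43 ± 0.185, SE) and 57.5% of WT in neural tube (-0.80 ± 0.168, SE). The edgeR adjusted p over all genes was 0.204 in heart and 0.989 in neural tube, so neither passed, while DESeq2 gave 0.00762 in neural tube. Adjusted over the list alone of 20 measured cohesin genes, Stag2 fell in neural tube (adjusted p = 0.00556) and did not pass in heart (0.212). The test of a difference in this effect between the tissues did not pass (adjusted p = 0.495). A 3′ tag that lies outside a deleted part of a gene says nothing about the protein, and the labels do not say which part was deleted.

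**Figure D2:**
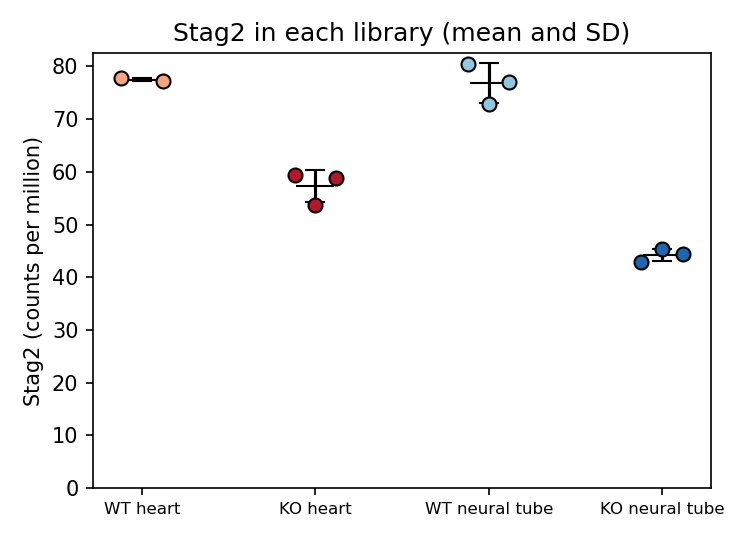
Stag2 level in CPM on an axis from 0, 1 point per library, with the mean and SD of each group. The KO libraries sit between 43.0 and 59.3 CPM and the WT libraries between 73.0 and 80.5 CPM.

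The other cohesin genes showed no common shift. Stag1, the paralogue that forms the alternative cohesin complex, was at 112 ± 6.8 CPM (SD, n = 3) in KO heart and 112 ± 7.8 (SD, n = 2) in WT heart. In neural tube it was at 143 ± 3.9 CPM (SD, n = 3) in KO and 121 ± 12 (SD, n = 3) in WT, a log2 fold change of 0.24 ± 0.167 (SE). Of the 20 measured list members, 10 had positive and 10 negative log2 fold changes in heart, and 7 had positive and 13 negative ones in neural tube. In heart the values included 1.23 ± 0.42 (SE) for Esco2, the acetyltransferase of S-phase cohesion, 0.65 ± 0.268 for the insulator protein gene Ctcf and 0.45 ± 0.212 for the ring subunit gene Rad21, with edgeR adjusted p of 0.132, 0.188 and 0.252. Rad21 was at -0.20 ± 0.187 (SE) and Ctcf at -0.21 ± 0.235 (SE) in neural tube. The list passed in neither tissue (camera adjusted p = 0.917 in heart and 0.324 in neural tube), and adjusted over the list alone 0 members passed in heart and 1, Stag2, in neural tube.

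The comparison of KO with WT heart asks what differs between the labelled genotypes in the heart region. In KO heart 12 genes rose and 16 fell. Smpx (ENSMUSG00000041476, chromosome X, 157698910 to 157752591), a small protein of striated muscle, fell from 282 ± 51 CPM (SD, n = 2) to 52.8 ± 8.2 (SD, n = 3), a log2 fold change of -2.42 ± 0.365 (SE). Nos3, the endothelial nitric oxide synthase, fell from 104 ± 76 CPM (SD, n = 2) to 8.0 ± 2.4 (SD, n = 3), and Cited1, a transcriptional co-regulator, fell from 71.1 ± 12 to 16.2 ± 1.7 CPM. Ngfr, a neurotrophin receptor of neural crest cells, fell from 17.6 ± 5.3 to 3.29 ± 1.9 CPM. Stmn4 (ENSMUSG00000022044, chromosome 14, 66344296 to 66361680), a microtubule regulator best known from neurons, rose from 5.37 ± 0.056 CPM (SD, n = 2) to 25.3 ± 7.7 (SD, n = 3), a log2 fold change of 2.24 ± 0.309 (SE).

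By the naming rule, 9 of the genes that rose and 10 of those that fell in KO heart were named. Besides Stmn4, the higher ones were the neuronal pentraxin gene Nptx2 (3.31 ± 0.593, SE), Grcc10 (2.06 ± 0.389), the mitochondrial carrier gene Slc25a47 (1.96 ± 0.34), Heph, a copper oxidase of iron export (1.93 ± 0.301), Dcaf6 (1.74 ± 0.32), the deubiquitinase gene Otub1 (1.57 ± 0.286), the homeobox gene Zfhx4 (1.38 ± 0.256) and Zfp668 (1.25 ± 0.224), all as log2 fold changes with SE. The lower ones besides Smpx, Cited1 (-2.13 ± 0.387), Ngfr (-2.35 ± 0.433) and Nos3 (-3.69 ± 0.586) were the nuclear envelope phosphatase gene Ctdnep1 (-2.99 ± 0.531), Ttll1 (-2.53 ± 0.476), Schip1 (-2.36 ± 0.398), the secreted factor gene Angptl2 (-2.03 ± 0.361), the sulfotransferase gene Chst8 (-2.03 ± 0.37) and the Rab regulator gene Tbc1d1 (-1.82 ± 0.325). The called genes outside the rule were Dcxr, Scarna10 and Gm38257, which rose, and Egfr, Actr3b, Gnao1, Slc35f6, Emilin2 and Fnbp1, which fell. For Nos3, Ctdnep1 and Ttll1 the WT hearts differed from each other, at 158 and 50.5 CPM for Nos3, at 728 and 197 CPM for Ctdnep1 and at 32.5 and 9.66 CPM for Ttll1. The edgeR adjusted p of the 28 called genes ran only from 0.0461 to 0.0487, while 2891 genes, 20.3% of those tested, had an unadjusted p under 0.05. DESeq2 called 800 genes, no filter gave 1112, the stricter filter 1 and a fit of the hearts alone 230. The count depended on single libraries, and edgeR called 0 genes without KO heart 1, WT heart 1, KO neural tube 2, WT neural tube 1 or WT neural tube 2, 1 without KO heart 2, KO heart 3 or WT neural tube 3, 117 without KO neural tube 1, 774 without KO neural tube 3 and 834 without WT heart 2.

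**Figure D3:**
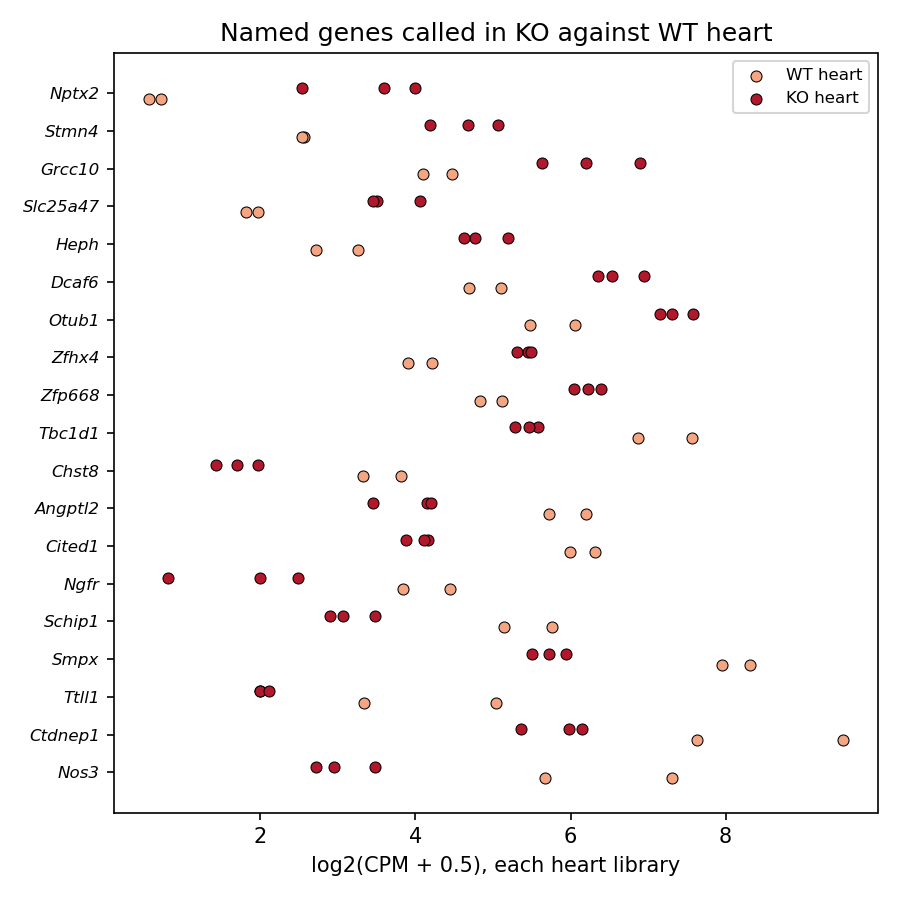
Level of the 19 named heart genes as log2 of CPM plus 0.5, 1 point per heart library. For each gene the 3 KO libraries lie on 1 side of the 2 WT libraries, which the naming rule required.

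Genes of the second heart field, the progenitors that add the outflow tract and right ventricle, had mostly lower values in KO heart. Of 24 measured members 19 had negative and 5 positive log2 fold changes, among them Wnt5a at 44.6 ± 2.9 CPM (SD, n = 3) in KO and 121 ± 24 (SD, n = 2) in WT (-1.43 ± 0.302, SE) and Prdm1 at -1.17 ± 0.321 (SE). Adjusted over the list alone these 2 genes passed, both lower, and over all genes 0 did. The list itself did not pass (camera adjusted p = 0.0604, and adjusted p = 0.965 with an estimated correlation). Its mean log2 CPM was 4.956 in WT heart 1, 4.442 in WT heart 2 and 4.029 to 4.333 in the KO hearts. Markers of pharyngeal and foregut endoderm, a neighbouring tissue, had 10 of 16 negative values in KO heart and a median of -0.495 (camera adjusted p = 0.249, with an unadjusted p under 0.05), with means of 3.923 to 3.96 in the KO hearts and of 4.434 and 4.215 in the WT hearts. Of 13 measured genes of retinoic acid signalling, which patterns the inflow of the heart, 12 had negative values. Cyp26b1, a retinoic acid hydroxylase, was at 85.7 ± 47 CPM (SD, n = 3) in KO and 205 ± 64 (SD, n = 2) in WT (-1.25 ± 0.349, SE) and passed over the list alone. This list missed in camera (adjusted p = 0.0802) and passed in fry (adjusted p = 0.0173), which asks whether the genes of a set move one way on balance.

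The mitochondrial genome list, with 7 of 9 members negative in KO heart, had a camera adjusted p of 0.0802, and mt-Rnr1 (-0.80 ± 0.229, SE), mt-Nd2 (-1.61 ± 0.394, SE) and mt-Nd4 (-1.16 ± 0.331, SE) passed adjusted over the list alone, all lower. Among 28 cardiac transcription factors 18 had negative values (0.197), and among 18 neural crest genes 12 had (0.197), with Ngfr lower. Of 31 measured contractile and calcium genes of cardiomyocytes, 19 had positive and 12 negative values (0.946). In that list Smpx was lower and Tcap, the titin cap, was higher over the list alone, at 1.20 ± 0.258 (SE). Of 20 genes of endocardial cushion and mesenchyme 12 were negative (0.346), and the collagen genes Col1a1 (-1.82 ± 0.392, SE), Col1a2 (-1.25 ± 0.291, SE) and Col5a1 (-0.90 ± 0.216, SE) passed over the list alone, all lower. Hypoxia and glycolysis genes had 19 positive values of 26 (0.249). Of 28 imprinted genes (0.553), 1 passed over the list alone as higher and 5 as lower, among them Dlk1 (-1.36 ± 0.326, SE) and Cdkn1c (-0.79 ± 0.272, SE), both growth regulators. Cytosolic ribosomal protein genes (0.441) moved both ways, with 11 higher and 9 lower over the list alone, and these transcripts share sequence with many pseudogenes, so their counts are less certain.

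The remaining heart lists had camera adjusted p of 0.37 for S phase, 0.437 for oxidative phosphorylation, 0.477 for Hedgehog targets, 0.517 for epicardium and proepicardium, 0.553 for somite and paraxial mesoderm and 0.631 for G2 and M phase. They were 0.671 for clustered protocadherins and for embryo sex genes, 0.758 for surface ectoderm, 0.792 for hepatic and yolk sac endoderm, 0.871 for early embryo stage genes and for endothelium and endocardium, 0.876 for the Notch pathway, Hox groups 6 to 13 and p53 targets, and 0.916 for primitive erythroid cells and Wnt targets. The BMP pathway, notochord, immediate early and heat shock genes, macrophages and other leukocytes, ventral neural tube, neural progenitors, differentiating neurons and Hox groups 1 to 5 were at 0.946, and dorsal neural tube was at 1.0. Thus 0 of 38 lists passed in camera, 7 had an unadjusted camera p under 0.05, 0 passed with an estimated correlation and 1 passed in fry. Camera called 3 lists without KO heart 2, WT heart 1 or WT heart 2, 1 without KO neural tube 1, 2 or 3 or WT neural tube 2 or 3, and 0 without KO heart 1, KO heart 3 or WT neural tube 1.

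The same question in the neural tube gave 0 called genes and 7 called gene lists. These calls assume a correlation of 0.01 between genes. The estimated correlations were higher, from 0.0208 for the dorsal list to 0.601 for the hepatic one, and with them 0 of the 7 held. Of the 10 splits of the neural tubes, 6 reached 7 called lists, the real one included, so the directions below are not shown to follow genotype. Contractile genes, which heart and skeletal muscle use to shorten, fell in KO neural tube, with 25 of 31 measured members negative and a median log2 fold change of -0.75 (camera adjusted p = 2.52e-13). With an estimated correlation the list had an adjusted p = 0.233. Adjusted over the list alone 4 members fell, namely the atrial myosin gene Myh6 (-2.70 ± 0.651, SE), the natriuretic peptide gene Nppa (-3.02 ± 0.904, SE), the myosin-binding protein gene Mybpc3 (-1.75 ± 0.467, SE) and Myh7 (-1.03 ± 0.309, SE). The levels were low and uneven, and WT neural tube 2 was the highest library for Nppa, Myh6, Mybpc3 and Myl3, at 5.27, 17.5, 18.8 and 41.8 CPM. The KO and WT libraries overlapped for Mybpc3 and Nppa. Outside that list, Des (ENSMUSG00000026208, chromosome 1, 75360329 to 75368579), the muscle intermediate filament, was at 33.9 ± 1.73 CPM (SD, n = 3) in KO and 62.8 ± 0.189 (SD, n = 3) in WT. Myh3, the embryonic skeletal muscle myosin, was at 5.64, 8.10 and 11.8 CPM in KO and at 15.5, 24.0 and 28.7 CPM in WT, while Myog, a skeletal muscle transcription factor, overlapped, with 6.76 to 26.7 CPM in KO and 11.9 to 37.5 in WT. Neither passed over all genes in edgeR (adjusted p = 0.989 for Des), and Myh3 and Myog were chosen after their values were seen.

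Dorsal neural tube genes fell in KO neural tube, with 11 of 13 members negative and a median of -0.48 (camera adjusted p = 0.00256, and adjusted p = 0.233 with an estimated correlation). The values were -0.70 ± 0.5 (SE) for the roof plate signal gene Wnt1, -0.64 ± 0.486 (SE) for the dorsal progenitor gene Pax7 and -0.53 ± 0.328 (SE) for the BMP target Msx1, and 0 members passed over the list alone. Genes of the mitochondrial genome fell as well, with 8 of 9 negative (camera adjusted p = 0.0324, and adjusted p = 0.444 with an estimated correlation). Second heart field genes rose, with 19 of 24 positive (camera adjusted p = 0.00148, and adjusted p = 0.457 with an estimated correlation), and Osr1, a mesoderm transcription factor, rose over the list alone (1.15 ± 0.285, SE). The mean log2 CPM of this list overlapped between genotypes, at 3.83, 3.287 and 3.382 in KO and 3.318, 2.759 and 3.509 in WT. Foregut endoderm genes had 11 of 16 positive values without a call (camera adjusted p = 0.401). Without KO neural tube 3 the dorsal list had an adjusted p of 0.0932 and the mitochondrial one 0.593, while the second heart field list stayed called (0.00784). The mean log2 CPM of the dorsal list was 2.959, 2.998 and 3.11 in KO neural tubes 1 to 3 and 3.458 to 3.585 in WT, without overlap. KO neural tube 3 was the KO library nearest to WT, so the lost dorsal call does not show that the fall rests on it. The second heart field list was not called without KO neural tube 1 (0.182) or WT neural tube 2 (0.263), and the mitochondrial one was not called without KO neural tube 2 (0.161), WT neural tube 1 (0.141) or WT neural tube 2 (0.0609).

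Hypoxia and glycolysis genes, cardiac transcription factors and hepatic and yolk sac genes rose in KO neural tube, with 24 of 26, 20 of 28 and 12 of 12 members positive. Their camera adjusted p were 9.19e-09, 0.00153 and 0.00148, and each call was lost with an estimated correlation (adjusted p = 0.444, 0.444 and 0.643). Over the list alone Pdk1, a kinase that inhibits pyruvate dehydrogenase (0.95 ± 0.242, SE), the phosphofructokinase gene Pfkp (2.06 ± 0.59, SE) and the vascular peptide gene Adm (2.40 ± 0.664, SE) rose in the first list, and members of the second that rose included Gata4 (3.08 ± 0.766, SE). For Pdk1, Pfkp and Adm the highest library was KO neural tube 3, at 86.6, 54.9 and 23.0 CPM, and Pfkp in KO neural tube 1, at 5.10 CPM, lay below the WT libraries, at 5.59 to 6.59. KO neural tube 3 stood apart in the hepatic and hypoxia lists. Its mean log2 CPM over the hepatic list was 1.81, against -0.80 to -0.39 in the other neural tubes, and over the hypoxia list it was 6.53, against 5.38 to 5.88. Over the cardiac list it was 3.27, against 2.46 to 3.08. The liver and yolk sac transcripts Afp and Ttr reached 8.58 and 9.11 CPM in it. Over Hox groups 6 to 13, which mark posterior levels of the body axis, its mean was 3.14, against -0.94 to 0.75, although that list did not pass (camera adjusted p = 0.229). Without KO neural tube 3 the 3 lists had adjusted p of 0.155, 0.311 and 0.849, the last with the direction turned to lower.

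**Figure D4:**
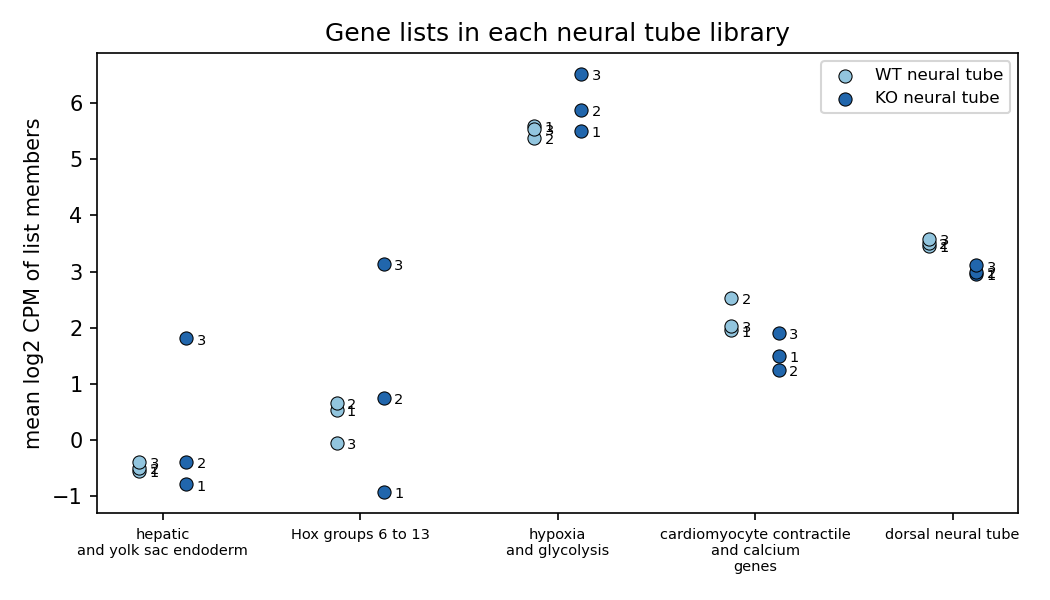
Mean log2 CPM of 5 gene lists in the 6 neural tube libraries, 1 point per library with its replicate number. KO neural tube 3 is the highest library for the hepatic list (1.81) and for Hox groups 6 to 13 (3.14).

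Over single genes edgeR called 0 in neural tube, with 523 at an unadjusted p under 0.05. DESeq2 called 4, voom with quality weights 3, limma-trend 0, and the edgeR fit with no filter 55. It called 1 gene without KO neural tube 3 or WT neural tube 3. The 5 genes with the smallest p were the replication histone gene Hist1h2al (3.02 ± 0.441, SE, adjusted p = 0.0874), Des (-0.89 ± 0.174, SE), the fatty acid desaturase gene Scd1 (-1.04 ± 0.213, SE), Stag2 and Tmem98 (1.29 ± 0.29, SE). Hist1h2al lay at 8.80 ± 3.0 CPM (SD, n = 3) in KO and 1.07 ± 0.26 (SD, n = 3) in WT, and Scd1 at 38.3 ± 1.5 (SD, n = 3) and 78.7 ± 9.9 (SD, n = 3). The other lists had camera adjusted p of 0.0693 for S phase, 0.091 for Wnt targets, 0.156 for neural crest, 0.229 for endocardial cushion and mesenchyme, 0.28 for leukocytes, 0.337 for neural progenitors and 0.374 for somite mesoderm and ventral neural tube. For the 21 lists that remained they ran from 0.401 for the BMP pathway and foregut endoderm to 0.92 for the Notch pathway.

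The mean of both genotype differences asks what KO embryos had in both tissues on average. It gave 5 called lists and 0 called genes. Hypoxia and glycolysis genes rose (22 of 26 positive, camera adjusted p = 2.04e-05), contractile genes fell (23 of 31 negative, 0.00067), mitochondrial genome genes fell (8 of 9 negative, 0.00067), neural crest genes fell (16 of 18 negative, 0.00727) and S phase genes fell (30 of 44 negative, 0.0304). With an estimated correlation these were adjusted p = 0.69, 0.69, 0.447, 0.447 and 0.447, so 0 of the 5 held, and fry called 0. Contractile genes had a median of -0.75 in neural tube and of 0.155 in heart, where 19 of 31 were positive. Their mean thus does not stand for a fall in both. Camera called the difference between the tissues (0.000463), but not with an estimated correlation (adjusted p = 0.862). Over the list alone the hypoxia members Pdk1 and Pfkp rose, and mt-Rnr1, mt-Nd2, mt-Nd4, Ngfr and Stag2 fell, the last by 0.62 on the log2 scale (adjusted p = 0.00382). Contractile genes were not called without WT heart 2 (0.0746), and neural crest genes were not called without WT heart 1 (0.324). S phase genes were not called without KO heart 3 (0.0792), KO neural tube 3 (0.095), WT heart 2 (0.161), WT neural tube 1 (0.0531) or WT neural tube 2 (0.0818). For single genes 1545 had an unadjusted p under 0.05 and the smallest edgeR adjusted p was 0.122, while DESeq2 called 98, voom with quality weights 2 and limma-trend 0, and edgeR called 165 without WT heart 2, 2 without KO heart 3 and 1 without KO neural tube 3 or WT neural tube 3.

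The difference between both genotype differences asks whether the heart and the neural tube responded differently. Second heart field genes had lower KO effects in heart than in neural tube, with 20 of 24 members negative (camera adjusted p = 0.000463), and contractile genes had higher ones, with 27 of 31 positive (0.000463). Cardiac transcription factors had 20 of 28 negative (0.00545) and hepatic genes 11 of 12 negative (0.0461). With an estimated correlation each had an adjusted p = 0.862, and fry called 0 lists. Pharyngeal and foregut endoderm genes had 12 of 16 negative values and a median of -0.715 in this comparison (camera adjusted p = 0.158, with an unadjusted p under 0.05). Over the list alone the second heart field members were Tbx1, Wnt5a, Eya1, Prdm1 and Osr1, all lower, and the contractile ones Mybpc3, Tcap, Myom1, Myh6 and Nppa, all higher. The first 2 lists stayed called without any single library, while cardiac factors were not called without KO neural tube 3 (0.277). Hepatic genes were not called without KO neural tube 3 (0.923), KO heart 2 (0.126), WT heart 2 (0.471) or WT neural tube 1 (0.111).

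For single genes the test of the difference called 0 in edgeR, with 2308 at an unadjusted p under 0.05. DESeq2 called 365, voom with quality weights 247 and limma-trend 0, and edgeR called 950 without KO neural tube 3 and 379 without WT heart 2. The 5 smallest p belonged to Stmn4 (2.59 ± 0.388, SE, adjusted p = 0.12), the perlecan gene Hspg2 (-2.81 ± 0.498, SE), Angptl2 (-2.79 ± 0.496, SE), Chst8 (-2.71 ± 0.485, SE) and Sarnp (-1.96 ± 0.356, SE). Of the 28 genes called in heart, 11 had the same sign in neural tube. An unadjusted p under 0.05 there was found for 3. Of these, Dcxr had the same sign (1.16 in neural tube), while Angptl2 (0.757) and Chst8 (0.685) had the opposite one. Across all 14226 genes, which are not independent replicates, the genotype log2 fold changes of the tissues had a Pearson correlation of -0.0355 and a Spearman correlation of -0.134, and 43.0% of genes had the same sign. The Pearson correlation ran from -0.202 without KO neural tube 3 to 0.0972 without KO neural tube 1, turning its sign, and was -0.139 with the stricter filter. Of genes with an unadjusted p under 0.05 in both tissues, 24 were higher in both against 26.5 by chance, 45 were lower in both against 26.5 and 87 were opposite against 53.3.

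The tissue comparison sets the scale of these differences. In WT, 1338 genes were higher and 918 lower in heart than in neural tube, and in KO 1126 were higher and 849 lower. The regulatory myosin light chain gene Myl2 was 1110-fold higher in WT heart than in WT neural tube (95% interval 538 to 2760), the muscle LIM protein gene Csrp3 682-fold (266 to 2510) and Smpx 639-fold (324 to 1480). Tnni3k, with no counts in WT neural tube, was at least 85.0-fold higher, and Klhl30, with 1 count there, was 703-fold higher (126 to 27800). The neural progenitor gene Zic1 was 632-fold lower in heart in the same measure (247 to 2320), the protocadherin gene Pcdh8, with 1 count, 305-fold (54.4 to 12100), and Myh3, Ntn5 and the neuronal factor gene Nhlh1, with no counts in WT heart, at least 97.2, 78.4 and 55.9-fold. Both tissue comparisons called 1159 genes in common against 313 by chance, 1152 of them in the same direction.

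Of the lists, 24 passed in camera between the WT tissues, and 8 of these held with an estimated correlation. Contractile genes rose in heart (30 of 31 called higher, camera adjusted p = 2.17e-139), as did cardiac transcription factors (21 called higher and 1 lower, 1.59e-32) and BMP pathway genes (9 and 1, 7.46e-07). Neural progenitor genes (17 called lower, 3.09e-23), neuron genes (17 lower and 1 higher, 9.9e-16), dorsal neural tube genes (10 lower, 1.46e-11), Hox groups 1 to 5 (9 lower, 9.45e-08) and somite genes (7 lower, 2.04e-07) were lower in heart. The second heart field list had 14 called higher and 1 lower (1.24e-05, and adjusted p = 0.116 with an estimated correlation), and hepatic and yolk sac genes had 10 called higher (1.24e-05, and adjusted p = 0.186 with an estimated correlation). The count of genes fell to 1491 without WT neural tube 2 in the WT comparison. In KO it was 1141 without KO neural tube 2, 1206 without KO heart 1, 1238 without KO heart 2 and 3101 without KO neural tube 3.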

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

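The tests of the shared library axis, of library quality, of transcript length and GC content, of expression level, of liver or yolk sac tissue, of the level along the body axis and of carried-over heart tissue were chosen only after the results were seen. The tests of liver or yolk sac tissue and of the level along the body axis replaced first versions that restated the pattern itself. The test of carried-over heart tissue replaced a first version that had used a lower tissue threshold, and its bound was then widened to the spread of the genes.

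In the test of the difference between the KO effects of heart and neural tube, camera with its preset correlation called 4 gene lists. These were second heart field genes, lower in heart than in neural tube (camera adjusted p = 0.000463), contractile and calcium genes, higher (0.000463), cardiac transcription factors, lower (0.00545), and hepatic and yolk sac genes, lower (0.0461). With an estimated correlation each had an adjusted p = 0.862, and fry called 0 lists. In camera without KO neural tube 3 the last 2 had 0.277 and 0.923. Hepatic genes were also not called without KO heart 2 (0.126), WT heart 2 (0.471) or WT neural tube 1 (0.111). Markers of pharyngeal and foregut endoderm went the way of the second heart field list without a call (12 of 16 negative, camera adjusted p = 0.158), so the amount of neighbouring tissue taken stays an open explanation.

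In heart, 2891 genes had an unadjusted p under 0.05 in edgeR between KO and WT, while 28 passed. The tables argue against depth (2669 such genes after all libraries were thinned to the smallest total, although called genes went from 28 to 53), against transcript length and 3′ GC content (Spearman correlations with the fold change across genes of -0.0186 and -0.0435), and against a loss of weakly expressed genes alone, since 26.1% of genes in the most expressed of 4 equal groups had such a p. An axis of variation learned on neural tubes alone, its sign set to go with the heart fold changes, correlated with them (Spearman 0.43 across genes, and 0.599 across those with a mean log2 CPM above 4). With it as a covariate 2452 genes had such a p and 24 of the 28 genes remained called. Their median absolute log2 fold change went from 2.05 to 1.83 (median SE from 0.363 to 0.34). However, the axis scores parted the hearts by genotype, at 10.9, 16.1 and 27.8 in KO and at -18.5 and -18.0 in WT. The covariate therefore cannot separate the axis from genotype in heart, and the axis stays open as a cause. Library quality stays open and cannot be told apart from genotype, since at equal depth the lowest KO heart had 1036 more detected genes than the highest WT heart and only 2 WT hearts were analysed. The 10 splits of the 5 hearts are too few for a share under 0.05, with 2891 genes in the real split, the 1 split with as many, and 1371 in the highest other, and a biological effect of genotype remains an untested explanation.

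Hepatic genes and Hox groups 6 to 13 were high in KO neural tube 3 among the neural tubes, where Afp and Ttr reached 8.58 and 9.11 CPM and 10 of 11 measured Hox genes were highest. The call of the hepatic list (adjusted p = 0.643 with an estimated correlation) went to an adjusted p of 0.849 without that library, with the direction turned. Liver or yolk sac tissue in the sample could give this, and of 24 further markers of these tissues 9 were measured and 4 were highest in that library, against 1.5 by chance (one-sided exact binomial p = 0.048), with a mean of 2.63 CPM against 2.25 in the other neural tubes. A section further back along the body axis could give the Hox levels, and of 12 markers of the hindbrain and further forward 8 were measured and 4 were lowest in that library, against 1.33 by chance (one-sided exact binomial p = 0.0307), with a mean of 8.45 CPM against 8.51. Genes of 1 library are not independent and the mean levels were close, so both explanations stay open hypotheses, as does a true difference of the embryos in that replicate.

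Contractile genes fell in KO neural tube in camera, with or without KO neural tube 3, but not with an estimated correlation (adjusted p = 0.233). Heart tissue carried into WT neural tubes could give this. The 30 heart genes outside the lists, over 64-fold higher in WT heart, had a median log2 fold change of 0.247 (SD 1.22), with 10 lower in KO. The contractile list had -0.75 (SD 0.786), with 25 of 31 lower. The gap was smaller than the spread across single heart genes, which is the widened bound, so the test was not taken to decide. Less somite muscle in the KO sections could give it too, and 11 measured markers of muscle, of 19 fixed for this test, had a median of -0.361 (SD 0.571), which lay between the bounds set for and against it. Without KO neural tube 3 these medians were -0.151 for heart genes, -0.889 for the contractile list and -0.187 for the muscle markers. The 10 splits of the 6 neural tubes are too few for a share under 0.05, with 7 lists called in the real split, reached by 6 of the 10 with it included, and 14 in the highest other, and a biological effect of genotype stays open and untested.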

How the results depend on the processing

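The library axis, voom with sample quality weights, the counts without Gm42418 and the lists of the mean and the difference without each library were tried only after the results were seen. The count of heart genes, 28 with edgeR, was 28 with RLE scaling, without haemoglobin and mitochondrial genes, without Gm42418 and with a log2 fold change of at least 1, 29 with limma-trend (22 of the 28 kept) and 31 with voom (16 kept). It was 800 with DESeq2, 1112 with no filter, 1 with the stricter filter, 230 with the hearts alone and 49 with the library axis. In neural tube the count of 0 became 4 with DESeq2, 55 with no filter, 1 with the library axis and 3 with voom. For the mean it became 98, 274, 8 and 2 in the same order, and for the difference 365 with DESeq2, 680 with no filter and 247 with voom. Limma-trend called 0 in these 3 comparisons, where edgeR had 523, 1545 and 2308 genes at an unadjusted p under 0.05. The tissue counts were 1367 in WT and 5305 in KO with voom. Fry called 1 list in heart and the library axis 2, and in neural tube an estimated correlation and fry each called 0 of the 7. Across genes the correlation of the genotype effects was -0.139 with the stricter filter. DESeq2 gave Stag2 in neural tube a log2 fold change of -0.7864 with an adjusted p of 0.00762, and over all settings that p ran from 0.00762 to 1. The cause of these changes was not tested, apart from the number of genes and libraries that the filters and the smaller fits set by construction.

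The labels do not say whether equal replicate numbers share embryos, so the numbers were not taken to pair the samples. With the number as a block, 0 heart genes and 1 heart list were called, and with a block of genotype by number 1389 genes were called between the WT tissues. In the pairing check, each library's deviations from its group mean were correlated across genes between heart and neural tube. Libraries of the same number gave 0.161, -0.136 and 0.149 in KO and 0.0211 and 0.0259 in WT, and KO libraries of different numbers gave -0.222 to 0.105. Among KO libraries, 1 and 3 correlated best with their own number and 2 did not, a hint from the data, not from the design. Pairs across genotypes, which cannot share embryos, reached 0.176 and 0.179, so correlations of this size are no evidence of shared embryos.

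Leaving out 1 library at a time moved the calls from 0 to 834 in heart, 0 to 1 in neural tube, 0 to 165 for the mean, 0 to 950 for the difference, 1491 to 2709 between the WT tissues and 1141 to 3101 between the KO tissues. The extremes were 834 and 165 without WT heart 2, 950, 2709 and 3101 without KO neural tube 3, 1491 without WT neural tube 2 and 1141 without KO neural tube 2. Lists called ran from 0 to 3 in heart and from 2 (without KO neural tube 3) to 11 (without KO neural tube 1) in neural tube. The hepatic list ran from 6.65e-08 to 0.849 in neural tube and turned its direction at 0.849, and the correlation ran from -0.202 without KO neural tube 3 to 0.0972 without KO neural tube 1. A WT heart left alone was assumed to vary like the other groups. Stag2 stayed lower in KO in every setting, from -0.39 to -0.46 in heart and from -0.72 to -0.83 in neural tube. Of the values for named genes under the planned settings, 192 lost the call, 81 gained one and 100, without a call, moved by more than 1 SE. The other 3630 kept their side of the threshold. Those of them without a call stayed within 1 SE, which does not fix their direction. Most named values had no call to lose in the main fit. Without KO heart 1 alone, 19 named values lost the call. As many did so with the replicate block and without KO heart 3, KO neural tube 2 or WT neural tube 1, 2 or 3. The stricter filter and the fit without KO heart 2 each lost 18. In counts simulated at these depths and this spread, a change of 1 log2 unit was found for 19% of changed genes in heart and 37% in neural tube, and one of 2 units for 84% and 97%. For the mean of both tissues a change of 1 unit was found for 66%, and for the difference between them for 4%. The changed genes were drawn from those with a mean of at least 10 CPM, and genes varied independently. Each gene had the same spread in all groups, WT heart included. These rates thus do not cover weaker genes, variation that genes share or a group that varies more than the others.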

Other observations

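The splits into other groups below were planned, except those that count genes with an unadjusted p under 0.05 for the mean of both tissues and for the neural tube, and these and the rest of the values here were looked at only after the results were seen.

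All 11 libraries held transcripts of the Y chromosome. Ddx3y, an RNA helicase, ran from 49.9 to 108 CPM, Uty from 34.6 to 70.9 and Kdm5d from 16.3 to 40.5, both linked to histone demethylation, and Eif2s3y from 5.24 to 9.52. Xist, the RNA that silences an X chromosome in female cells, had 0 to 12 counts per library, at most 1.98 CPM. Among X-linked partners in KO heart, the demethylase genes Kdm6a and Kdm5c had log2 fold changes of 0.86 ± 0.296 (SE) and 0.72 ± 0.211 (SE), and Eif2s3x, a translation factor subunit, had -2.24 ± 0.493 (SE, adjusted p = 0.0593). Adjusted over the list alone of 8 embryo sex genes, 4 were higher and 1 lower in KO heart.

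In KO heart, where 20.3% of all tested genes had an unadjusted p under 0.05, 4 of 23 measured endothelial genes passed adjusted over the list alone and 0 over all genes. Of these, Etv2, which starts the endothelial program (1.38 ± 0.306, SE), and Ramp2 (0.84 ± 0.27, SE) were higher, and the natriuretic peptide receptor gene Npr3 of the endocardium (-0.87 ± 0.191, SE) and the VEGF receptor gene Flt1 (-0.93 ± 0.266, SE) were lower. The list did not pass (camera adjusted p = 0.871). Etv2 lay at 37.3 ± 6.8 CPM (SD, n = 3) in KO and 14.2 ± 4.3 (SD, n = 2) in WT. Krt8, a keratin of simple epithelia (-1.64 ± 0.413, SE), and the junction gene Cldn4 (-1.23 ± 0.342, SE) were lower over the foregut endoderm list alone. Of the p53 targets, Mdm2, which restrains p53, was lower over the list alone (-1.23 ± 0.311, SE).

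Other groupings of the same libraries were fitted with edgeR for the remaining counts. For single genes called in neural tube the real split gave 0, a count that each of the 10 splits reaches by construction, so that test decides nothing. The highest other split there called 228 genes, with KO 1, KO 2 and WT 1 against the rest, which points to a structure among these samples other than genotype. At an unadjusted p under 0.05 the real neural tube split had 523 genes, reached by 4 of the 10 with it included, and the highest other 2814, and 10 splits are too few for a share under 0.05. The count of called genes for the mean of both tissues was 0 as well, which all 100 draws reach by construction, with 983 in the highest other. With genes at an unadjusted p under 0.05 chance cannot be excluded for the mean, since 10 of the 100 draws, the real one included, gave as many as its 1545, with 3776 in the highest other. For the KO tissue difference the 10 splits are again too few, with 1975 genes in the real split, which was the 1 split with as many, and 0 in the highest other.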
